A study of Solanum lycopersicum with 10 samples.

How the data were processed

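Total RNA from 10 stages of flower and fruit of tomato cultivar Micro-Tom was measured on 10 Affymetrix tomato GeneChip arrays, 1 per stage, after labelling with a kit for 3' in vitro transcription. Plants were grown in pots in a growth chamber, and RNA was extracted with phenol and chloroform. The deposited values are log2 expression values per probe set, made by the authors with RMA from the affy package according to the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a probe set, and the notes give no versions or settings. The values ran from 2.37 to 14.90, and no value was missing, shifted or transformed further.

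The table held 10209 probe sets. The 108 Affymetrix control probe sets were left out of the tests and used as array measures only, and the 63 reporter probe sets for bacterial and other foreign genes were kept and served as the background level. For each array, this level was the 95th percentile of the reporters, from 4.15 on the open flower to 5.63 on the +7 days array, with 8760 (87.3%) and 7317 (72.9%) probe sets above it. Hybridization control means ran from 9.00 to 11.06 between arrays and 17S ribosomal RNA from 8.94 to 13.07. The 3' minus 5' difference of the EF1a controls was 1.74 to 1.86 from 1-3 mm to mature green fruit and 2.02 to 2.28 from breaker on. For GAPDH it was 0.12 to 0.97 and 0.86 to 1.06, and for actin -0.40 to 0.11 and -0.11 to 0.01. A bias to the 3' end can thus not be told apart from stage between these fruit, and its effect was not tested. Arrays have no read depth, and their number limits the precision.

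Gene symbols came from the array annotation of 2007 in the reference tables. It paired 909 probe sets with 1 gene symbol, none with several, and left 9192 of the tested probe sets without a gene. Of the 909, 885 were matched by gene identifier to the current gene table of assembly SLM_r2.1, which was used for names and synonyms alone. No coordinates are given, since the array files name no genome build. The 909 probe sets stood for 803 genes, and 82 genes had several probe sets, of which the one with the highest mean over all arrays was used.

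The stages were grouped into 3 phases before the data were examined: flower (closed bud, open flower), pre-breaker fruit (1-3 mm, 5-7 mm, 11-14 mm, mature green) and ripening fruit (breaker, +3, +5 and +7 days). Each probe set was fitted with the 3 phases as coefficients in limma 3.58.1 under R 4.3.3, with lmFit and eBayes (7 residual and 2.33 prior degrees of freedom). The 2 contrasts, ripening minus pre-breaker and pre-breaker minus flower, were tested with limma's moderated statistic, two-sided, with Benjamini-Hochberg adjustment over the 10101 probe sets and a threshold of 0.05. The contrasts share the 4 pre-breaker arrays. The residual is the spread between stages of a phase, so it holds development as well as biological and technical noise. Steps between single arrays were counted by a log2 difference of at least 1 and have no test.

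Of 29 gene lists written before the data were examined, 20 had at least 3 genes that the annotation paired with a probe set, 5 had 1 or 2 and 4 had none. A further 7 lists were written after the gene names of the array were seen and before their values were. Lists were tested in the 2 contrasts with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of a contrast. For 4 untested steps, the median of each list was placed among 10000 random lists of equal size and matched expression level. The outer 2.5% at either end as a mark was chosen later. Camera and the random lists drew on the 803 named genes alone and not on all probe sets. Named genes were chosen by a rule fixed beforehand. In a tested contrast it took the 8 highest and 8 lowest differences among named probe sets past the threshold whose phases did not overlap, and in a step the 6 highest and 6 lowest among those above the median of all values (7.97) on 1 of the arrays. It added the members of largest difference of each list described, and a set of ripening and flower genes where the tables name them.

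The tests were checked on simulated data with 50 changed probe sets per size among 10101. The noise was drawn independently for each probe set and array, at the probe set's residual spread. It held no order between stages, so the shares below do not cover errors that come from development within a phase. For ripening against pre-breaker fruit, 12%, 72%, 88% and 98% were called at log2 differences of 1, 2, 4 and 8, with 13 of 9901 unchanged probe sets called. For pre-breaker fruit against flower the shares were 4%, 36%, 84% and 94%, with 3 of 9901 called. Alternatives covered scaling (quantile, median, cyclic loess and, added later, hybridization controls), filters on dim probe sets, the eBayes prior, the arrays used, the threshold, probe sets averaged per gene, the place of breaker, stage order and the omission of each array. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.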

Results

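Messenger RNA was measured on 10 Affymetrix tomato GeneChip arrays, 1 for each of 10 stages of flower and fruit of Micro-Tom, a dwarf tomato cultivar. The stages were closed bud, open flower, fruit of 1-3 mm, 5-7 mm and 11-14 mm, mature green fruit, breaker fruit (the first change of colour), and fruit 3, 5 and 7 days after breaker. Buds and flowers were taken whole, with sepals, petals, stamens and carpels, and the labels do not part the tissues of the fruit. For the tests, the stages formed 3 phases: flower (2 arrays), pre-breaker fruit (4 arrays, 1-3 mm to mature green) and ripening fruit (4 arrays, from breaker). No stage had a replicate, so the number of arrays limits the precision, and a difference between phases was tested against the spread between the stages of a phase. The median of an array lay between 7.90 and 8.02 on the log2 scale. Of the 10101 probe sets tested, 909 were paired with 1 gene symbol, and genes are named from these alone.

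PG2, the polygalacturonase that degrades pectin, had the largest measured rise among named genes from pre-breaker to ripening fruit, from 3.20 ± 0.33 (SD, n = 4) to 13.95 ± 0.91 (SD, n = 4) on the log2 scale, a difference of 10.74 (SE 0.43, adjusted p = 3.33e-06). AAT, an alcohol acyltransferase that makes ester volatiles, rose from 3.15 ± 0.19 (SD, n = 4) to 13.53 ± 0.65 (SD, n = 4), by 10.38 (SE 0.32, adjusted p = 5.89e-07). RIN, a MADS-box regulator of ripening, rose from 3.64 ± 0.26 (SD, n = 4) to 12.32 ± 1.10 (SD, n = 4), by 8.68 (SE 0.48, adjusted p = 3.78e-05). TPRP-F1, a proline-rich protein of young fruit, had the largest measured fall among named genes, from 12.04 ± 2.58 (SD, n = 4) to 4.04 ± 0.73 (SD, n = 4), a difference of -8.00 (SE 1.09, adjusted p = 0.00377). This comparison addresses which transcripts part ripening fruit from growing and mature green fruit.

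The other genes with the largest rises were Man4, an endo-beta-mannanase of the cell wall, the expansin EXP1, hdc (histidine decarboxylase), the ethylene-responsive E8, and ACS4, an ACC synthase that makes the precursor of ethylene. Man4 rose by 9.43 (adjusted p = 7.35e-05), EXP1 by 8.68 (adjusted p = 7.02e-05) and hdc by 8.50 (adjusted p = 0.00361). E8 rose by 7.91 (adjusted p = 0.00175) and ACS4 by 7.75 (adjusted p = 0.00277). The other large declines were in TPP3 (-7.45, adjusted p = 0.0165), the Aux/IAA gene IAA16 (-6.44, adjusted p = 0.000389), yfe37, also listed as GAD3, a glutamate decarboxylase (-6.01, adjusted p = 0.0138), and LOC543961, also listed as SUS1, a sucrose synthase (-5.89, adjusted p = 0.00307). Prg1 fell by 5.83 (adjusted p = 0.0201), gad2 fell by 5.78 (adjusted p = 0.00727) and ARPI fell by 5.70 (adjusted p = 0.0109). By the rule of choice, every ripening array lay beyond every pre-breaker array for each of these 16 genes. PG2, AAT, Man4, RIN, hdc and ACS4 in pre-breaker fruit were above the level of the reporter probe sets for foreign genes on at most 1 of 4 arrays. The same held for TPRP-F1, TPP3, IAA16, yfe37, Prg1 and ARPI in ripening fruit. Their differences may thus understate the change, and the order among these genes is uncertain. LOC543961 was above the reporter level on 2 of the 4 ripening arrays.

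Among genes fixed for mention beforehand, the carotenoid gene Psy1 rose by 4.76 (adjusted p = 0.00148), while 1 of its 3 probe sets ran the other way, at -0.87 (adjusted p = 0.209). The NAC regulator NOR rose by 6.25 (adjusted p = 0.00361), the lipoxygenase loxC by 6.19 (adjusted p = 0.00331), the MADS-box genes TDR4 by 3.83 (adjusted p = 0.0269) and TAGL1 by 1.09 (adjusted p = 0.0275), and LOC544279, the ethylene receptor ETR3, by 3.11 (adjusted p = 0.0162). ACS2, a further ACC synthase, differed by 4.94 (SE 1.68) without passing the test (adjusted p = 0.0663), and the floral organ gene AG1 differed by -0.34 (adjusted p = 0.598). CNR, ACO1, E4, LAT52 and RBCS were not paired with a probe set.

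**Figure D1:**
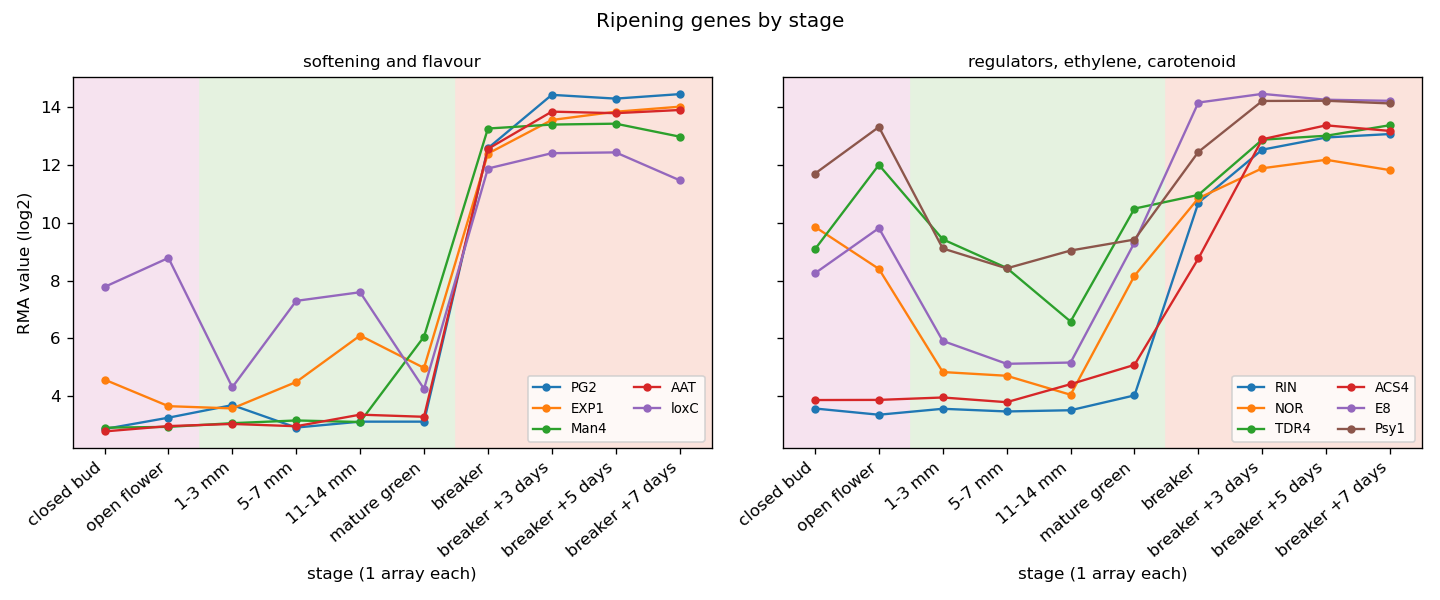
RMA value (log2, vertical axis) of 11 ripening genes by stage (horizontal axis), with 1 point per array and the flower, pre-breaker and ripening phases shaded from left to right. PG2 was at 3.11 on the mature green array and at 12.58 on the breaker array, while Psy1 was also high in the open flower, at 13.32.

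All 4 ripening regulators paired with a probe set rose (RIN, NOR, TDR4 and TAGL1), with a median of 5.04 (camera adjusted p = 0.00276; adjusted p = 0.349 with an estimated correlation), and the same 4 were called adjusted over the list alone. In the lycopene pathway, 4 of 6 members rose and 2 did not pass, also when adjusted over the list alone. The examples are Psy1, the plastid oxidase PTOX (2.37), the desaturases ZDS (2.04) and PDS (1.93), and the median was 1.98 (camera adjusted p = 0.0171; adjusted p = 0.602 with an estimated correlation). Of 9 genes of flavour volatiles, 4 rose, 1 fell and 4 did not pass; 6 were higher and 2 lower adjusted over the list alone. AAT, the lipoxygenase LOXB (7.58), loxC and the alcohol dehydrogenase ADH2 (1.39) rose and the lipoxygenase loxD, which works in jasmonate synthesis, fell (-3.90), with a median of 1.51 for the list (camera adjusted p = 0.0223; adjusted p = 0.349 with an estimated correlation).

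Of 5 auxin genes, all of the Aux/IAA family, 4 fell and 1 did not pass, also adjusted over the list alone. IAA17 (-5.52), IAA2 (-2.92), IAA27 (-2.42) and IAA7 (-1.83) fell, and the median was -2.42 (camera adjusted p = 0.0223; adjusted p = 0.349 with an estimated correlation). In the cell cycle list, 3 of 9 genes fell, with 7 called lower adjusted over the list alone. These were the kinases CDKA1 (-3.96) and CDKB1 (-2.47) and the cyclin CYCD3 (-2.49), at a list median of -1.87 (camera adjusted p = 0.023; adjusted p = 0.602 with an estimated correlation). The cell cycle call was lost without the 11-14 mm or the breaker array, the flavour call without breaker, and the auxin call without mature green or breaker.

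The list of pectin disassembly also held the mannanases Man4 and MAN1, which are not pectin genes by name. Its genes went both ways: 6 of 12 rose, 2 fell and 4 did not pass (7 higher and 2 lower adjusted over the list alone). PG2, Man4, the pectin methylesterase PME2.1 (4.58) and the beta-galactosidases TBG3 (3.38) and TBG4 (3.07) rose, and PMEU1 (-5.34) and TBG7 (-3.34) fell. Camera did not call this list (adjusted p = 0.0741), whereas fry, which tests whether members move on balance 1 way and compares with no other gene, did (adjusted p = 0.000183). Among 12 genes of wall loosening, EXP1 and the xyloglucan endotransglucosylase XTH5 (3.09) rose, 5 fell, led by XTH16 (-5.64), XTH1 (-5.20) and the expansin EXP5 (-4.79), and 5 did not pass. That list was not called (camera adjusted p = 0.322), with 4 higher and 6 lower adjusted over the list alone.

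Of 18 genes of ethylene perception and response, E8, LOC544279 and the receptor ETR2 (2.68) rose and the response factor ERF3 (-3.67) fell, the same 4 adjusted over the list alone (camera adjusted p = 0.0741). Among 10 genes of ethylene synthesis, ACS4 rose and ACS6 (-5.44) and the ACC oxidase ACO4 (-2.50) fell, with 2 higher and 2 lower adjusted over the list alone. Here the median (-0.30) and the direction of camera were negative and the mean (0.30) positive (camera adjusted p = 0.752). Of 16 genes of sucrose and hexose metabolism, the acid invertase AI (3.26) rose and 5 fell, led by LOC543961 and the hexokinase hxk1 (-2.98), with the same counts adjusted over the list alone (camera adjusted p = 0.17; fry adjusted p = 0.0455). The starch gene AGP-S2 (1.07) rose and AgpL1 (-4.98) fell among 3 (camera adjusted p = 0.607; 1 higher and 2 lower adjusted over the list alone).

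CAB4 (-2.98, adjusted p = 0.0455) was the only one of 3 light-harvesting genes to pass the test, at a list mean of -2.97 (camera adjusted p = 0.2). The lack of a call does not mean that the other members held their level. All 3 were at least 1 log2 lower from mature green to breaker and again from breaker to +7 days, untested. None of 5 photosystem genes passed, at a list median of -1.50 (camera adjusted p = 0.347). LCY1, the lycopene beta-cyclase that converts lycopene, fell (-2.05, adjusted p = 0.00679), the single call among 7 genes of carotenoid cyclisation (camera adjusted p = 0.539; 1 higher and 1 lower adjusted over the list alone). The small heat shock gene HSP21 rose by 5.82 among 3 genes (camera adjusted p = 0.277), and the osmotin-like NP24-I (6.09) and LOC543878 (2.86) rose among 9 defence genes (camera adjusted p = 0.106). Of 6 gibberellin genes, 20ox-3 (3.31) rose and GA20OX1 (-3.37) fell (camera adjusted p = 0.703), and of 6 floral MADS-box genes, TDR8 (2.78) rose and TDR6 (-2.54) fell (camera adjusted p = 0.562). No member passed among 4 pollen and anther genes (camera adjusted p = 0.752) or 3 flavonoid genes (camera adjusted p = 0.703). Counts adjusted over the list alone were equal to these in the lists of this paragraph other than carotenoid cyclisation. The calls of CAB4 (lost in 15 of 25 alternative settings, highest adjusted p = 0.222), GA20OX1 (14 of 24, 0.177), HSP21 (13 of 25, 0.205), CDKB1 (13 of 24, 0.208), hxk1 (11 of 24, 0.242) and PME2.1 (10 of 25, 0.189) depended on single arrays and on other choices. Some list members named as falling were above the reporter level on at most 1 of the 4 ripening arrays. These were IAA17, IAA2, IAA7, CDKA1, CDKB1, TBG7, XTH1, EXP5, ACS6, AgpL1 and GA20OX1. LOC543878 was likewise above it on at most 1 pre-breaker array, so all these differences may understate the change.

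Lists with 1 or 2 members were not tested as lists. The chlorophyll synthesis gene POR2 differed by 0.64, the fruit protein gene 2A11, the only pistil list member, by 0.82, the lipid transfer genes TSW12 and LE16 by -1.27 and -1.95, and the reference genes ACT and TUB by 0.14 and -2.55. None passed over all probe sets, and TUB alone passed adjusted over the list alone. 2A11 had the highest value of all tested probe sets on the 5-7 mm, 11-14 mm, +3, +5 and +7 days arrays. Its difference may thus be held down by the upper end of the scale. The steroidal alkaloid list held gad2 and GABA-TP2 (-5.45, adjusted p = 0.0111), both lower. Their symbols name glutamate decarboxylase and GABA transaminase, while the gene table gives them the alkaloid names GAME11 and GAME12 as synonyms. The lists of Calvin cycle, histone, ribosomal protein and seed storage genes had no member paired with a probe set by the annotation, which does not show that such genes are missing from the array.

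In all, 1859 of 10101 probe sets changed between pre-breaker and ripening fruit (limma, adjusted p under 0.05), 1089 higher and 770 lower, of which 203 had a gene name (97 higher, 106 lower). By 2 log2 or more, 263 were higher and 550 lower. The phases did not overlap for 2345 probe sets (23.2%), against 2.86% if arrays fell into the phases at random. The stages are ordered, so a gradual change also parts the phases, and 2.86% is not a chance rate for these data. The median difference of all probe sets was 0.19 as deposited, -0.01 after cyclic loess and -0.22 after scaling on hybridization controls. The share of calls that were higher was 58.6%, 43.4% and 19.8% in the same order. It was 62.0% after quantile scaling and 55.9% after median scaling. The 63 reporter probe sets differed by a median of 0.44 between the phases, and 2 of them were called higher. The count fell to 55 without the 5-7 mm and +7 days arrays, whose control probe sets stood apart, where 7 of the 16 genes named by rank kept their call. Without single arrays it was 644 (5-7 mm), 1070 (11-14 mm), 3017 (mature green), 471 (+3 days), 444 (+5 days) and 450 (+7 days), with 13 to 16 of the 16 genes called.

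FRK4, a fructokinase of stamens, had the largest measured fall among named genes from flower to pre-breaker fruit, from 13.62 ± 0.56 (SD, n = 2) to 3.67 ± 0.68 (SD, n = 4), a difference of -9.95 (SE 0.43, adjusted p = 8.73e-07). Shy, a protein of the pollen tube, fell by 9.60 (SE 0.51, adjusted p = 3.49e-06) and TPI, a MADS-box gene of petal and stamen identity, fell by 8.98 (SE 0.37, adjusted p = 7.99e-07). The fruit protein gene 2A11 rose most, from 8.77 ± 3.14 (SD, n = 2) to 14.01 ± 1.11 (SD, n = 4), by 5.24 (SE 1.06, adjusted p = 0.03), a call that was lost in 12 of 23 alternative settings (highest adjusted p = 0.224). Its values in 5-7 mm and 11-14 mm fruit were the highest of all tested probe sets on those arrays, so the rise may be understated. This comparison addresses which transcripts part the growing fruit from the whole flower, which also holds organs that the fruit lacks.

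LIN7, a cell wall invertase of anthers, fell by 8.34 (adjusted p = 5.48e-06) and PRK2, a receptor kinase of pollen, fell by 8.17 (adjusted p = 2e-05). LOC543717 fell by 6.95 (adjusted p = 0.000117), PRO1, listed also as the profilin LePro1, fell by 5.95 (adjusted p = 2.17e-05) and abz1 fell by 5.91 (adjusted p = 0.0224). Another gene carries the symbol PRO1 too, and the values here belong to the one with that synonym. Besides 2A11, the named genes that rose were ADH2 by 2.71 (adjusted p = 0.00513), help1 by 2.24 (adjusted p = 0.0187), the transcription factor gene WRKYIId by 1.64 (adjusted p = 0.0138) and the malic enzyme gene ME2 by 1.56 (adjusted p = 0.00877). By the rule of choice, every pre-breaker array lay beyond both flower arrays for these 13 genes. FRK4, Shy, TPI and PRK2 were above the reporter level on at most 1 of the 4 pre-breaker arrays. Their differences may thus understate the change, and their order is uncertain. Psy1 fell by 3.51 (adjusted p = 0.0127), with 1 of its 3 probe sets at 0.43 (adjusted p = 0.814), and NOR differed by -3.70 without passing (adjusted p = 0.11). Of the other genes fixed for mention, RIN, PG2, EXP1, ACS2, ACS4, E8, loxC, TDR4, TAGL1, AG1 and LOC544279 did not pass.

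**Figure D2:**
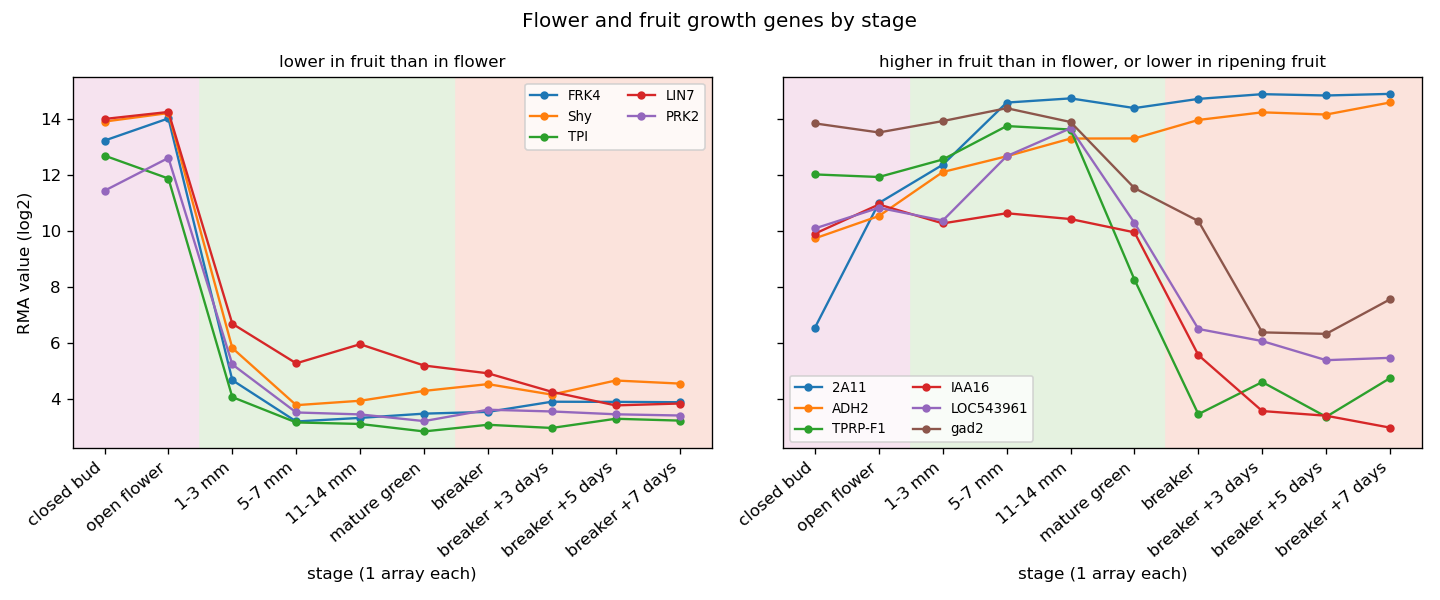
RMA value (log2, vertical axis) of 11 genes named in the comparisons of flower, pre-breaker and ripening fruit (shaded from left to right) by stage (horizontal axis), with 1 point per array. FRK4 was at 14.01 in the open flower and at 4.67 in 1-3 mm fruit, and IAA16 was at 9.95 on the mature green and 5.56 on the breaker array.

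In the lycopene pathway, 2 of 6 genes fell from flower to pre-breaker fruit, Psy1 and PDS (-2.61, adjusted p = 0.015), and 5 were lower adjusted over the list alone. The list median was -1.94 (camera adjusted p = 0.00217; adjusted p = 0.66 with an estimated correlation). Of 4 pollen and anther genes, PRK2 and PRK1 (-4.82, adjusted p = 0.000204) fell, the same 2 adjusted over the list alone, with a median of -2.79 (camera adjusted p = 0.0217; adjusted p = 0.66 with an estimated correlation). Both list calls were lost without the open flower array, and the pollen call also without mature green. PRK1 was above the reporter level on 0 of the 4 pre-breaker arrays, so its difference may understate the change.

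The other 18 lists were not called by camera, with adjusted p from 0.191 for floral MADS-box genes to 0.951 for ripening regulators. Of these, fry called the floral MADS-box list (adjusted p = 0.00174) and sucrose and hexose metabolism (adjusted p = 0.00331). In the floral MADS-box list TPI fell and 5 did not pass (2 lower adjusted over the list alone), and in sucrose and hexose metabolism FRK4 and LIN7 fell and 14 did not pass (1 higher and 4 lower adjusted over the list alone). The auxin gene IAA7 (-3.77) fell, as did NSY, also listed as Cyc-B, of the carotenoid cyclisation list (-2.32, a call lost in 11 of 22 alternative settings). The cyclin gene CycA1 (-2.59) and the ACC synthase gene ACS8 (-2.63) fell too, and ADH2 was the single rise among flavour genes. ACS8 was above the reporter level on 1 of the 4 pre-breaker arrays, so its difference may understate the change. Adjusted over the list alone, 3 auxin genes were higher and 1 lower, 2 ethylene synthesis genes were lower, 1 ripening regulator was higher and 1 lower, and 1 heat shock gene was higher. Median, mean and camera differed in sign for ethylene synthesis (0.07, -0.64, down), ethylene perception (0.00, -0.14, up), the cell cycle (0.22, -0.02, up) and starch (-0.03, 0.19, up).

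In all, 303 of 10101 probe sets changed from flower to pre-breaker fruit (limma, adjusted p under 0.05), 34 higher and 269 lower, of which 53 had a gene name (5 higher, 48 lower). The phases did not overlap for 2203 probe sets (21.8%), against 13.3% if arrays fell into the phases at random. As the stages are ordered, 13.3% is not a chance rate for these data either. The median difference of all probe sets was 0.17 as deposited, 0.04 after cyclic loess and -0.07 after scaling on hybridization controls. Of the lower calls, 128 were above the reporter level on fewer than 4 arrays, and 116 probe sets were called when such probe sets were left out. The count was 131 from the arrays of the compared phases alone, where 7 of the 13 genes named by rank kept their call, as did 7 without the closed bud array. The number of higher calls moved most. It was 2 from the compared phases alone, 5 after scaling on hybridization controls and 96 without the 1-3 mm array.

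Between successive single arrays, values are given without a test. The arrays from +3 days on were the most alike: 405 probe sets differed by at least 1 log2 between +5 and +7 days (204 higher, 201 lower) and 523 between +3 and +5 days (155 higher, 368 lower). The largest steps were from open flower to 1-3 mm fruit (1625 higher, 1537 lower), from 11-14 mm to mature green fruit (1544 higher, 1575 lower) and from 1-3 mm to 5-7 mm fruit (1515 higher, 1579 lower). From 5-7 to 11-14 mm, 1028 were higher and 881 lower, and from breaker to +3 days 633 were higher and 1023 lower. Pearson's r across probe sets, which are not independent replicates, ran from 0.871 for open flower to 1-3 mm fruit to 0.985 for +5 to +7 days. The smallest step holds the noise between single arrays as well as development.

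**Figure D3:**
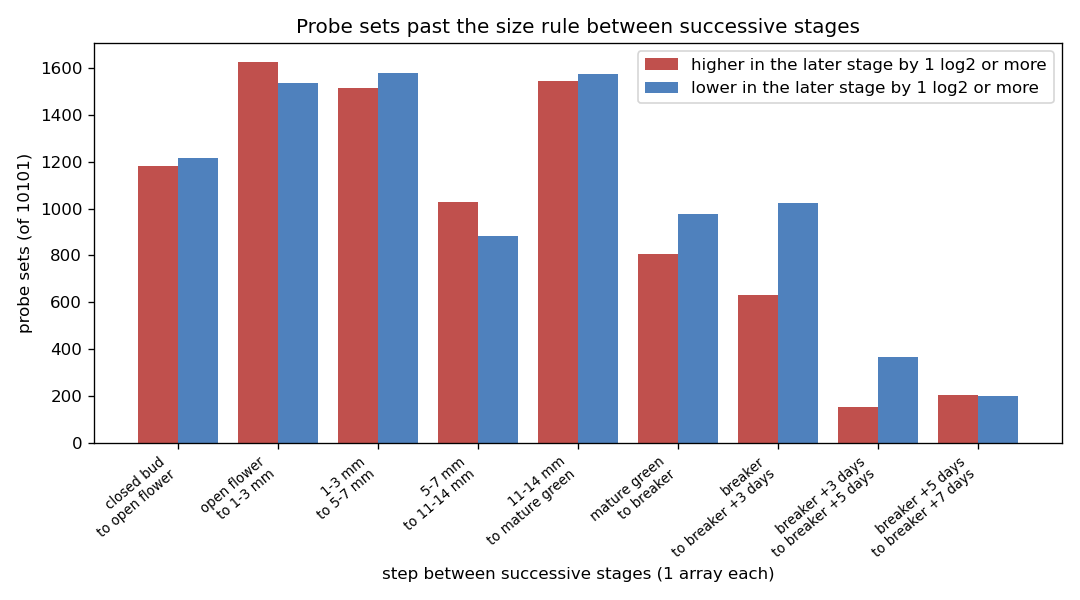
Number of probe sets (vertical axis, of 10101) at least 1 log2 higher or lower in the later of the stages named on the horizontal axis, each from 1 array, without a test. The step from breaker to +3 days had 633 higher and 1023 lower, and the step from +5 to +7 days 204 higher and 201 lower.

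From closed bud to open flower, the ethylene gene ACS2 stood 6.37 log2 higher, at 4.04 and 10.41, and the polygalacturonase gene TAPG4 4.45 higher. 2A11 (4.44), the ribonuclease gene RNALE (4.06), the NAC gene JA2 (4.05) and the ethylene receptor ETR6 (4.01) followed. The malate dehydrogenase gene cMDH was lower by the most (-4.79), then the mannanase gene MAN2 (-3.47), RSI-1 (-3.19), the expansin genes exp18 (-3.13) and exp9 (-2.91), and GP1 (-3.02), a polygalacturonase beta subunit. ACS2 and TAPG4 were under the reporter level in the bud. The list medians were 0.99 for ethylene synthesis (higher than 99.3% of random lists of equal size and level), 0.90 for ethylene perception (98.5%) and 1.26 for defence (99.3%). They were -0.80 for pectin disassembly (higher than 0.93% of random lists) and -1.63 for auxin (0.68%). In this step 1180 probe sets were higher by at least 1 log2 and 1216 lower, with 1 array against 1 and no test.

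From 1-3 mm to 11-14 mm fruit, genes of light harvesting and the photosystems were higher. The medians were 4.78 for light harvesting (higher than 99.9% of random lists), 3.43 for photosystems (99.9%), 3.27 for starch synthesis (99.6%), 1.17 for pectin disassembly (99.2%), 1.16 for wall loosening (98.8%) and 1.21 for gibberellin (98.5%). CAB5 was at 6.40 and 11.19, CAB6A at 8.10 and 12.89, PsbQ at 9.30 and 12.73, and the starch gene AgpL1 at 7.73 and 12.58. The named genes higher by the most were MT2, a metallothionein (6.26), XTH7 (6.25), XTH1 (5.91), the MADS-box gene AGL11 (5.34), GA20OX1, an enzyme of gibberellin synthesis (5.01), and XTH6 (5.00). Defence genes were lower, with a median of -4.84 that lay below all 10000 random lists, and the medians were -1.54 for ethylene synthesis (higher than 0.32% of random lists) and -1.17 for ethylene perception (1.71%). TLRP (-7.12), cathDInh, a protease inhibitor (-6.33), the lipid transfer gene TSW12 (-6.17), LOC544276, an isocitrate lyase (-6.14), PR-P2, a pathogenesis-related protein (-6.03), and LOC543602 (-5.89) were the lowest. AGL11, GA20OX1 and XTH6 at 1-3 mm, and LOC544276, PR-P2 and LOC543602 at 11-14 mm, were under the reporter level, so the order among these genes is uncertain. These values rest on 1 array against 1 and were not tested.

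From mature green to breaker fruit, the named genes higher by the most were PG2 (9.47, at 3.11 and 12.58), AAT (9.28), loxC (7.63), EXP1 (7.43), Man4 (7.21) and RIN (6.68, at 4.02 and 10.70). The lowest were IAA17 (-5.95), GA20OX1 (-5.09), TPRP-F1 (-4.80), MT2 (-4.78), IAA16 (-4.38) and LOC543961 (-3.79). List medians were 1.58 for ripening regulators (higher than 99.3% of random lists), 1.44 for flavonoids (99.6%), 1.00 for flavour volatiles (98.9%), 0.75 for ethylene synthesis (99.7%) and 0.57 for ethylene perception (98.1%). They were -2.70 for light harvesting (higher than 0.53% of random lists), -1.82 for auxin (0.43%) and -0.85 for photosystems (0.34%). The flavonoid genes CHS2 and CHS1 were at 11.18 and 7.46 on the mature green and at 12.62 and 10.20 on the breaker array. DFR, the remaining member of that list, was at least 1 log2 lower at breaker, where it was under the reporter level. PG2, AAT, loxC and RIN were under the reporter level on the mature green array, and GA20OX1 and TPRP-F1 on the breaker array. Their differences may thus understate the change, and their order is uncertain. This step at the onset of ripening held 805 probe sets at least 1 log2 higher and 977 lower, 1 array against 1 and untested.

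From breaker to +7 days, Cel2, an endoglucanase of the cell wall, was 8.04 higher, hdc 5.65, ACS2 5.35, ER1 5.07, the xylosidase gene XYL1 4.61 and ACS4 4.42. GP1 (-6.24), the photosystem gene PsbQ (-6.23), CAB6A (-5.88), PMEU1 (-5.34), and the lipid transfer genes LE16 (-4.94) and ltpg1 (-4.82) were the lowest. XYL1 at breaker, and CAB6A and PMEU1 at +7 days, were under the reporter level. The medians were -3.90 for light harvesting (higher than 0.16% of random lists), -2.47 for photosystems (0.86%), -2.30 for flavonoids (1.62%) and -0.73 for sucrose and hexose metabolism (2.09%). They were 1.68 for ripening regulators (99.7%), 0.96 for the lycopene pathway (98.9%), 0.75 for defence (97.9%) and 0.42 for ethylene perception (97.6%). Over the 4 untested steps compared by list, 30 of 80 medians fell in the outer 2.5% at either end. Random lists hold unrelated genes, while members of a list can vary together and some steps share an array, so this count and the percentiles are descriptions and not tests.

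**Figure D4:**
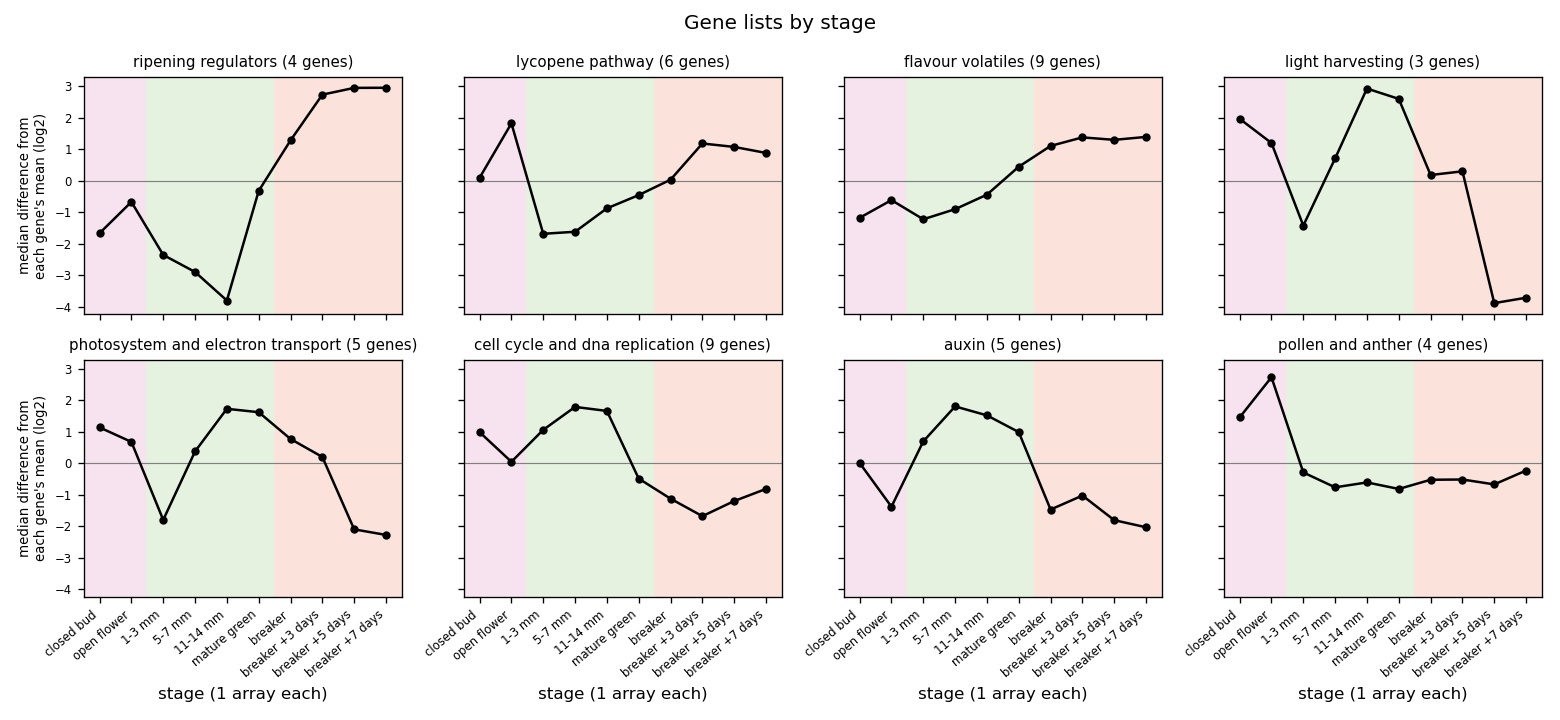
Median over the members of 8 gene lists of each gene's log2 difference from its own mean over the 10 arrays (vertical axis) by stage (horizontal axis), with 1 point per array and flower, pre-breaker and ripening phases shaded from left to right. The 3 light-harvesting genes had a median of 2.93 at 11-14 mm and -3.89 at +5 days, and the 4 ripening regulators 1.28 at breaker and 2.73 at +3 days.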

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

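The splits of the arrays and the scaling test for mature green fruit were set before their results were seen, while the tests of omitted pairs, of admixture, of probe sets of nearest level, of dim probe sets and of the share of higher calls were chosen after seeing the result. Values were searched within the phases of 4 arrays for an array far from the others, by Dixon's 95% critical value. Of 158 such tests 20 stood out, against 7.9 if chance marked 1 in 20. That figure holds for independent tests on replicates. Here the 4 arrays of a phase are ordered stages, the tests share arrays, and many genes were chosen by their phase differences. The excess over 7.9 is therefore not evidence that an array is unusual.

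On the breaker array, several ripening genes lay below the other ripening arrays: PG2 at 12.58 (nearest 14.30), AAT at 12.56 (13.80), hdc at 7.91 (13.42), ACS4 at 8.76 (12.90), Psy1 at 12.46 (14.14), ACS2 at 7.99 (12.98) and LOC544279 at 9.92 (12.57). FRK4 was at 3.54 there (nearest 3.88), near background, and TPP3 at 6.68 was above the nearest at 4.49. The ripening regulators had a list median of 1.28 relative to each gene's mean at breaker (nearest 2.73), and the wound and protease inhibitor list -1.25, above the others. On the mature green array, Man4 was at 6.05 (nearest 3.15), RIN at 4.02 (3.56), TPP3 at 6.77 (13.92), yfe37 at 7.04 (12.02) and the heat shock list at 2.75 (nearest -1.53). In 1-3 mm fruit, 2A11 was at 12.36 (nearest 14.38) and PRK2 at 5.23 (3.52). The hybridization control mean was 11.06 at +7 days (nearest 9.89), and 17S ribosomal RNA 13.07 in 5-7 mm fruit (nearest 10.54).

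Of the 35 splits of the 8 fruit arrays into 4 and 4, 1, the real one, gave as many as 1859 changed probe sets. The highest other split gave 96 and differed only by exchanging mature green and breaker. The stages follow an order in development, so a gradual change along it would also put the real split first. The rank therefore does not exclude chance, and it shows only that this split gave the most calls. For gene lists, 3 of the 35 splits gave at least the 5 lists of the real one, with 5 as the highest other, so chance is not excluded there either.

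The count of changed probe sets in ripening against pre-breaker fruit (1859) fell to 55 when the 5-7 mm and +7 days arrays, whose controls stood apart, were left out. Their technical state is argued against as the main cause, since leaving out 1 pre-breaker and 1 ripening array while keeping these arrays, mature green and breaker gave 123 to 245. A candidate explanation is that the mature green and breaker arrays widen the spread within phases: the 9 pairs whose omission keeps both gave 53 to 248, and the 7 that leave out 1 or both gave 1555 to 3537. For the rest of the drop, the technical state of the 5-7 mm array and its stage cannot be told apart, since the 3 pairs without it gave 53 to 55, the others that keep mature green and breaker at least 123, and the stage has 1 array. Whether a biological transition or noise of the mature green and breaker arrays widens the spread stays open as well.

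Some ripening transcripts were already raised on the mature green array. Breaker tissue in that sample as the only source is argued against. The 11 probe sets compared were low in young fruit and abundant at breaker. Of these, 81.8% lay more than 4-fold from their median share of the breaker level (14.5%). NOR stood at 14.5% of its breaker level and Man4 at 0.588%. RIN and AAT were under the reporter level and so at most at 1.5% and 0.41%. The highest shares, 353% and 262%, exceeded the breaker level itself. Shares are also uneven if some transcripts start before breaker while a trace of breaker tissue is present. Such a trace is not excluded, as for Man4, whose share was near the limit for AAT. Shares were taken against breaker fruit alone, so riper tissue was not tested. Of the 1089 higher calls, 76 stood at least 2 log2 above the 11-14 mm array, as did 467 of all 10101 probe sets. The median of the 76 was 2.87, and 2.85 after cyclic loess, which moved none by more than 0.11. They were picked by this difference on arrays already normalized. Cyclic loess could therefore hardly remove it, and it does not decide on scaling. The 100 other probe sets nearest in level to a member had a median of at most 0.41. No shift of 2 log2 shared by probe sets of like level was thus seen. That these genes start before breaker may be a biological difference between stages, which 1 array per stage leaves untested.

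More calls were higher than lower in ripening fruit (58.6% as deposited). Raised levels of dim probe sets are argued against as the only cause, since among the 952 calls above the median level 60.4% were higher. Dim probe sets did lean to higher calls, with 76 higher and 3 lower above the reporter level on under 4 arrays. Among probe sets above that level on at least 4 arrays the share was 55.8%. It was 54.2% at a log2 difference of at least 1 and 49.8% at an adjusted p of 0.01. By 2 log2 or more, 263 were higher and 550 lower. The share also depended on the scaling. It was 62.0% after quantile and 55.9% after median scaling, 43.4% after cyclic loess and 19.8% after scaling on hybridization controls. Cyclic loess evens out differences between arrays by design, so its result does not show that scaling caused the excess. Scaling between arrays stays a possible cause. Leaving out single arrays gave 49.0% (without +3 days) to 59.1% (without breaker). Whether total messenger RNA per sample differed between the phases stays open, as the arrays do not measure it.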

How the results depend on the processing

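Scaling on hybridization controls, the omission of the 5-7 mm and +7 days arrays together and the filter on reporter level were added after seeing the data. No called result changed direction under any alternative run. No paired analysis was possible because each stage has 1 array.

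The count for ripening against pre-breaker fruit (1859) stayed within 1.5 times, from 1554 to 1974, under quantile, median and cyclic loess scaling, the other prior, without the lowest-expressed quintile, from the compared phases alone, at a log2 difference of at least 1, above the reporters and with breaker counted as pre-ripening (1871, of which 1146 shared). It was 952 above the median level, 176 per gene among named probe sets and 315 at an adjusted p of 0.01, which test fewer probe sets or ask for more. It was 878 after scaling on hybridization controls, 2940 with stage order, 3537 without mature green and breaker and 55 without the 5-7 mm and +7 days arrays. Leaving out single arrays gave 444 (without +5 days) to 3017 (without mature green), with 471 without +3 days, 450 without +7 days, 644 without 5-7 mm and 1070 without 11-14 mm. The count for pre-breaker fruit against flower (303) was 38 above the median level, 144 without the lowest-expressed quintile, 50 per gene, 173 at 0.01, 131 from the compared phases, 183 without the 5-7 mm and +7 days arrays and 116 above the reporters. Leaving out single arrays gave 224 to 418.

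Of the 29 genes named by rank, 10 remained called above the median level, where 12 were tested, and 16 without the 5-7 mm and +7 days arrays, and single omissions left 23 to 29. The 7 list calls all ended (0) with an estimated correlation, while single omissions gave 4 (without breaker) to 9 (without 1-3 mm). Steps past a log2 difference of 1 were counted 1782 times from mature green to breaker, 481 at 2 and 914 above the median level. For closed bud to open flower the count was 2396, with 603 at 2 and 1130 above the median level, and over all 9 steps it was 18046, with 5062 at 2. List medians in the outer 2.5% were 30, and 29 both per gene and after cyclic loess. Except where fewer probe sets, arrays or a stricter threshold account for it, the cause was not tested. Signal over background limits the dim genes, as 869 probe sets were above the reporters on no array.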

Other observations

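The list tests here were not planned: the 7 lists of this part were written after the gene names of the array were seen, and the patterns by stage were noticed in the values. The adjusted p of single genes are those of the planned comparisons. From pre-breaker to ripening fruit, of 6 jasmonate genes OPR3 (-4.22, adjusted p = 0.0162) and loxD (-3.90, adjusted p = 0.0347) fell, the receptor gene COI1 rose (1.20, adjusted p = 0.0204) and 3 did not pass, at a median of -3.35 (camera adjusted p = 0.266; fry adjusted p = 0.136). AOS, the allene oxide synthase, was at 9.34 in 11-14 mm fruit and 3.77, under the reporter level, in mature green fruit. Of 8 wound and protease inhibitor genes, LAPA1, a leucine aminopeptidase (-4.60, adjusted p = 0.0476), LOC543954, a protease inhibitor (-4.33, adjusted p = 0.0214), and the arginase gene ARG2 (-4.26, adjusted p = 0.0325) fell and 5 did not pass (camera adjusted p = 0.266; fry adjusted p = 0.0331). Its members TD2 and cathDInh were at 14.44 and 14.15 in the closed bud and at 9.03 and 5.85 in 11-14 mm fruit. LOC543954 and ARG2 were above the reporter level on at most 1 of the 4 ripening arrays, so their differences may understate the change.

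Of 5 genes of GABA metabolism, yfe37, gad2 and GABA-TP2 fell and GABA-TP1 (1.64) and GABA-TP3 (0.28) did not pass, at a median of -5.45 (camera adjusted p = 0.266; fry adjusted p = 0.0193). As gad2 and GABA-TP2 also form the steroidal alkaloid list, under alkaloid synonyms, their place in GABA metabolism is uncertain. Among 15 antioxidant genes, FESOD, an iron superoxide dismutase (3.53), and GSH1, of glutathione synthesis (2.60), rose, and DHAR1 (-1.75), GLDH (-1.12) and APX1 (-0.99) fell, with a median of 0.03 and a camera direction of down (camera adjusted p = 0.865). FESOD has 2 probe sets, and the other differed by 0.49 (adjusted p = 0.627). Of 7 meristem genes T6 fell (-3.20), at a median of 0.15 and a mean of -0.30 (camera adjusted p = 0.865). T6 was above the reporter level on 1 of the 4 ripening arrays, so its difference may understate the change. Of 5 metallothionein genes MTA fell (-2.29; camera adjusted p = 0.865), and MT2 stood at 5.55 in 1-3 mm, 13.53 in mature green and 8.75 in breaker fruit. Of 6 malate genes ME2 fell (-0.93, adjusted p = 0.0199; camera adjusted p = 0.865), at a median of 0.19 and a mean of -0.04. From flower to pre-breaker fruit none of these 7 lists was called (camera adjusted p from 0.447 to 0.956), and ME2 was their single call.

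CAB4 was at 12.93 in the open flower, 9.07 in 1-3 mm fruit and 13.22 in 11-14 mm fruit, and PSBO at 12.51, 9.81 and 13.34. Within ripening fruit, CAB6A was at 10.26 at +3 days and 4.45 at +5 days, and PsbQ at 10.90 and 6.97; CAB6A was under the reporter level at +5 days. Between 11-14 mm and mature green fruit, the lipoxygenase gene LOX1.1 was at 3.26, under the reporter level, and 12.35, the pectin methylesterase gene PE1 at 5.63 and 13.83 and HSP21 at 6.47 and 12.46, and XTH1 was at 13.86 and 7.19. These values rest on single arrays.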
